A study of Mus musculus with 8 samples.

How the data were processed

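Total RNA from C2C12 cells, a mouse myoblast line that fuses into myotubes in culture, was measured on Affymetrix Mouse Gene ST arrays. Per the labels, the myoblasts carried a retrovirus with either a scrambled control shRNA or an shRNA against Baf60c (gene symbol Smarcd3, a subunit of the BAF chromatin remodelling complex). They were differentiated into myotubes and kept for 12 h at a glucose concentration of 1 mM or of 10 mM. The 8 arrays form 4 groups of 2 samples, which the series design describes as independent biological replicates.

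The deposited table held 1 log2 expression value for each of 41345 probe sets on each array, made by the authors from the scanned intensities with the RMA method and the affy package, per the submitters' processing notes. The package version and the genome build behind the probe set design were not given in the sources used here. The deposited log2 values ran from 0.0556 to 13.6, and the median of the tested genes lay between 5.89 and 6.02 on the 8 arrays, so no further normalization was applied. RMA normalizes arrays to a common distribution and shrinks differences at low intensity. The fold change of a dim gene may therefore be understated, and a change shared by all transcripts would not be visible. The number of arrays limits the precision of every value.

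Probe sets were named from the platform annotation. Of the 41345 probe sets, 23521 were assigned to exactly 1 gene, 1814 to several genes and 16010 to none. Gene IDs of 23328 of those 23521 matched the reference gene table of mouse assembly GRCm38.p6, which was used for symbols alone and changed 0 of them. A gene with more than 1 probe set (1082 of 22180 genes) was represented by the probe set with the highest mean over all 8 arrays. Genes whose mean lay below the 40th percentile, a log2 value of 2.30, were left out, which left 13308 genes. Probe sets with several genes or none entered no comparison of genes. The knockdown target was the exception. Smarcd3 was on the array only through a probe set assigned to both Chpf2 and Smarcd3, and its values are reported as those of the shared probe set, fitted together with the tested genes.

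Gene comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options) with 1 mean per group over all 8 arrays, which left 4 residual and 3.36 prior degrees of freedom. The 5 contrasts were 10 mM against 1 mM glucose in control myotubes and in knockdown myotubes, knockdown against control at 1 mM and at 10 mM glucose, and the interaction, which is the glucose response in knockdown cells minus that in control cells. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 13308 genes, and a gene was called at an adjusted p under 0.05. The glucose contrasts share no arrays with each other, nor do the knockdown contrasts. Errors of fold changes are the standard errors (SE) of the log2 change from this fit. The overlap of calls between contrasts was set beside the overlap of independent lists of the same sizes.

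Gene lists, 31 in number with 676 genes, of which 586 were tested and 2 stood in more than 1 list, were fixed before the data were examined. They cover pathways of glucose, lipid, amino acid and stress metabolism, muscle differentiation and fibre types, and markers of other cell types. Each list was tested in each contrast with camera from limma at its preset inter-gene correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation. With an estimated correlation, 2 of the 15 list calls for the glucose response in control cells held, 1 of 13 in knockdown cells, 0 of 10 and 0 of 6 for the knockdown effects at 1 mM and 10 mM glucose, and 0 of 2 for the interaction. The fry test, which asks whether the members of a list move on balance in 1 direction and does not compare them with other genes, was past the threshold for 23, 25, 11, 6 and 0 lists in the same order. In camera, the estimated setting raised p also where the estimate was below 0.01. For the NRF2 and pentose phosphate list in control cells the estimate was -0.0236, and the camera p went from 2.57e-10 to 0.00259. A call lost with this setting therefore does not by itself show that members were correlated. The counts of list members given below come from the adjustment over all genes, and counts adjusted over the list alone stand beside them.

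The genes named in the text followed a rule fixed before the data were examined. It took 8 genes in every contrast (Smarcd3, Smarcd1, Smarcd2, Deptor, Txnip, Arrdc4, Hk2 and Slc2a4). It added up to 10 genes per direction with the largest change among called genes whose replicates did not overlap between groups, and up to 4 called members per list with the smallest p. Where under 10 genes were called, it took 5 per direction with the smallest unadjusted p, named as not called. Predicted genes, clone names, small RNAs and olfactory or vomeronasal receptors were skipped among the largest changes. A few genes were added after their values were seen, as is said where they are named.

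The procedure was tested on simulated data in which 200 of the 13308 genes were given known changes. Of genes changed by 1 on the log2 scale, 51% were recovered for the glucose response in control cells, 58% in knockdown cells, 59% and 54% for the knockdown at 1 mM and 10 mM, and 3% for the interaction. For changes of 2 on the log2 scale the shares were 87%, 94%, 88%, 92% and 77%. The simulated false calls made up 3.5%, 2.56%, 3.92%, 2.67% and 1.23% of the calls. In the data 3372 and 3342 genes were called for glucose in control and knockdown cells, far more than the 200 simulated. The Benjamini-Hochberg adjustment is less strict when more genes change. The simulated shares for glucose therefore do not describe how many glucose changes were missed in the data.

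Alternatives chosen before the data were examined were no filter on dim genes, a stricter filter at the 60th percentile, eBayes with an intensity trend and robust prior, renewed quantile normalization of the tested genes, centring each array on the median of its tested genes, the mean over the probe sets of a gene, the replicate number as a block, a fit of the 4 arrays of a contrast alone, the estimated correlation in camera, and leaving out each array in turn. Chosen after seeing the data were the fit of the shared target probe set, list members at a middle expression level, families of genes with a common symbol stem, and the probe sets without a single gene. No scan date or batch was given in the sources used here, so none could be tested. Other splits of the samples were not counted, since no group holds 3 samples.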

Results

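The data are 8 expression arrays of C2C12 myotubes, 2 biological replicates in each of 4 groups: control or Baf60c knockdown, each kept for 12 h at a glucose concentration of 1 mM or of 10 mM. Replicates correlated at r = 0.988, 0.988, 0.987 and 0.990 across genes in control cells at 1 mM, control cells at 10 mM, knockdown cells at 1 mM and knockdown cells at 10 mM, and arrays of different groups at 0.939 to 0.984 (genes are not independent replicates). The first principal component held 62.8% of the variance and separated the glucose levels, and the next held 13.5% and separated knockdown from control. The median standard error of a log2 change was 0.173, so its 95% confidence interval reached 0.406 to either side, and 0.574 for the interaction. Unless stated otherwise, changes below are log2 changes ± SE from limma with n = 2 arrays per group.

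The knockdown target was examined first, as a check of the labels. The probe set shared by Smarcd3 (Baf60c) and Chpf2 (17446269) read 5.62 and 5.40 in the control replicates at 1 mM glucose and 3.01 and 2.77 in the knockdown replicates. At 10 mM it read 6.27 and 6.09 in control and 3.90 and 4.49 in knockdown cells. It was therefore 6.15-fold lower after knockdown at 1 mM (-2.62 ± 0.22, adjusted p = 0.00313) and 3.95-fold lower at 10 mM (-1.98, adjusted p = 0.0171). With glucose it changed by 0.67 in control cells (adjusted p = 0.060) and rose 2.48-fold in knockdown cells (adjusted p = 0.00442), and the difference between these, 0.64 ± 0.30, did not pass the test (adjusted p = 0.673). Because the probe set covers both genes, the share of Smarcd3 in the signal was not resolved. The related subunits Smarcd1 and Smarcd2 were not called in any contrast. Their changes lay between -0.29 and 0.34, and a second probe set of Smarcd1, also not called, was at 0.74 with glucose in control cells (adjusted p = 0.182) and at 0.59 in knockdown cells (adjusted p = 0.283). The target signal in knockdown cells at 1 mM lay near the lower end of the scale, so the fold there may be understated.

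**Figure D1:**
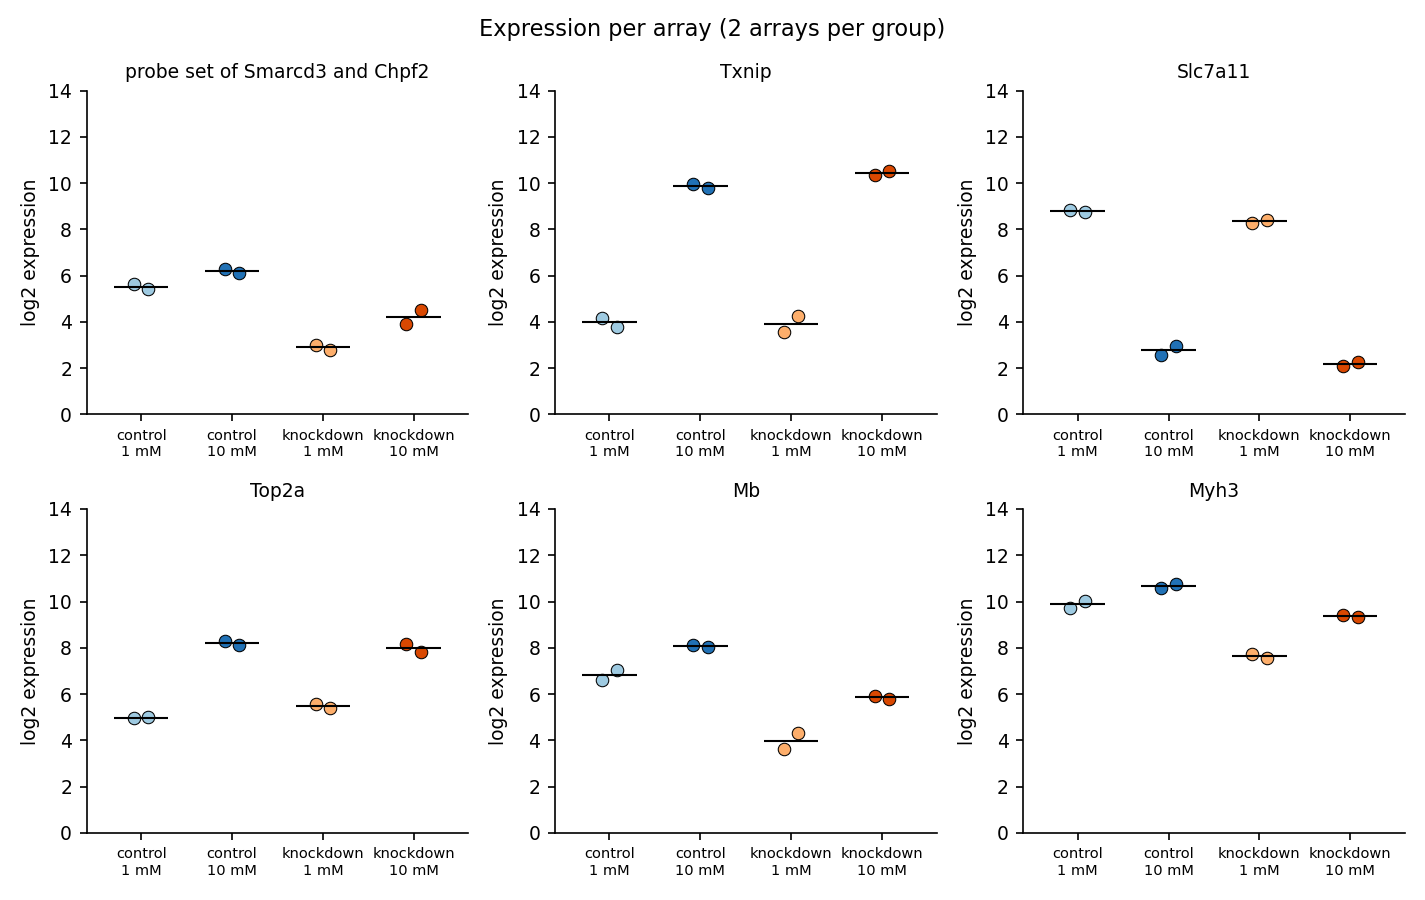
Log2 expression (vertical axis) of the shared Smarcd3 and Chpf2 probe set and of 5 genes on each of the 8 arrays; each point is 1 array and each line the mean of the 2 arrays of a group. Txnip rose and Slc7a11 fell with glucose in both cell types, and Mb and Myh3 were lower after knockdown at both glucose levels.

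The comparison of 10 mM with 1 mM glucose in control myotubes asks how expression differs between cells kept at a low and at a higher concentration. Rises and falls with glucose are values at 10 mM relative to 1 mM. Different samples were kept at each concentration, so whether 10 mM lowered a gene or 1 mM raised it was not resolved. Most measured genes of the amino acid response and of the endoplasmic reticulum stress response fell, and most measured cell cycle genes rose. Txnip, a glucose-induced inhibitor of glucose uptake, rose 59.4-fold (5.89 ± 0.24, adjusted p = 4.53e-05, n = 2 per group). Slc7a11, the cystine transporter, fell 65.8-fold (-6.04 ± 0.16, adjusted p = 8.7e-06), to dim signal at 10 mM. Cth, which makes cysteine from cystathionine, fell 24.1-fold (-4.59 ± 0.12). In all, limma called 3372 of 13308 genes, 1761 higher and 1611 lower at 10 mM, and 1341 of them by at least 2-fold. The split turned with each array centred on its median (1591 higher, 1840 lower) and with a stricter filter (1686 and 1766).

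The list of ATF4 targets and amino acid response genes fell broadly. Of 33 measured members, 31 fell, 0 rose and 2 did not pass the test, and 31 fell when adjusted over the list alone. Besides Slc7a11 and Cth, the pseudokinase gene Trib3 fell 20.2-fold and the stress transcription factor gene Ddit3 (CHOP) 10.4-fold. The list's median change was -2.20 (camera adjusted p = 4.33e-27, and adjusted p = 0.0401 with an estimated correlation). Chaperones of the endoplasmic reticulum and the unfolded protein response fell in 20 of 21 measured members, also when adjusted over the list alone. Sdf2l1 fell 18.0-fold, Hyou1 7.06-fold and the chaperone gene Hspa5 (BiP) by 2.77 ± 0.15 on the log2 scale. The median was -1.72 (adjusted p = 1.77e-17, but adjusted p = 0.0786 with an estimated correlation). Of 13 NRF2 target and pentose phosphate genes, 11 fell and 2 did not pass, with 11 adjusted over the list alone. Gclm, a subunit of the enzyme that starts glutathione synthesis, fell 4.16-fold and the heme oxygenase gene Hmox1 3.81-fold. The median was -1.38 (adjusted p = 1.99e-09, and adjusted p = 0.0401 with an estimated correlation). Of 21 interferon response genes, 7 fell, 0 rose and 14 did not pass, with 7 adjusted over the list alone, among them Usp18 (-1.53 ± 0.22) and Ifit1 (-1.41 ± 0.28). The median was -0.37 (adjusted p = 0.00443, but adjusted p = 0.151 with an estimated correlation).

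Cell cycle genes rose in 21 of 28 measured members and fell in 0, while 7 did not pass. Adjusted over the list alone, 23 rose and 1 fell. Top2a rose 9.53-fold (3.25 ± 0.16) and the mitotic kinase gene Bub1 and the kinesin gene Kif20a by 3.03 ± 0.21 and 2.92 ± 0.16. The median was 1.93 (adjusted p = 7.38e-13, but adjusted p = 0.166 with an estimated correlation). Some muscle genes rose at the same time. Of 26 genes of myogenic differentiation, 15 rose and 11 did not pass, and 16 rose when adjusted over the list alone. Among them, the fusion factor gene Mymx rose 3.85-fold, the myogenic regulator gene Myod1 4.58-fold and the creatine kinase gene Ckm 2.32-fold. Their median was 0.68 (adjusted p = 4.75e-08, but adjusted p = 0.166 with an estimated correlation). In the fast fibre list 7 of 14 members rose and 7 did not pass (9 rose adjusted over the list alone). Among the rises were the myosin genes Myh4 (5.56-fold) and Myh1 (2.42-fold). The median was 0.64 (adjusted p = 0.000214, but adjusted p = 0.169 with an estimated correlation). In the slow fibre list 6 of 13 rose, 6 did not pass and the calcium pump gene Atp2a2 fell (-1.02 ± 0.14), with 10 rises and 1 fall adjusted over the list alone. Tnnt1 rose by 1.35 ± 0.19 and the myoglobin gene Mb by 1.26 ± 0.24. The median was 0.62 (adjusted p = 0.00255, but adjusted p = 0.169 with an estimated correlation).

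Extracellular matrix genes rose in 16 of 26 members and fell in 0, also when adjusted over the list alone, and 10 did not pass. Col8a1 rose 3.57-fold and Thbs1 by 1.67 ± 0.13. The median was 0.77 (adjusted p = 4.75e-08, but adjusted p = 0.0973 with an estimated correlation). Markers of other cell types were read beside these groups. In the fibroblast and smooth muscle list, 5 of 11 rose, 1 fell and 5 did not pass, with 6 rises and 1 fall adjusted over the list alone. The dermatopontin gene Dpt rose 5.0-fold and the smooth muscle actin gene Acta2 by 1.20 ± 0.14. The median was 0.35 (adjusted p = 0.0182, but adjusted p = 0.166 with an estimated correlation). Undifferentiated myoblast markers went both ways, with 5 rises, 2 falls and 9 members not past the test. Adjusted over the list alone, 6 rose and 3 fell. Hmga2 fell by 1.88 ± 0.14 and Cd34 rose by 1.24 ± 0.16, and the median of 0.13 did not stand apart (adjusted p = 0.431). None of the 7 macrophage markers was called by limma, over all genes or adjusted over the list alone (median -0.10, adjusted p = 0.40). Of 9 adipocyte markers 2 fell (3 adjusted over the list alone), Pnpla2 (-0.85 ± 0.13) and Plin4 (-0.68 ± 0.18), at a list median of -0.26 (adjusted p = 0.384).

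Single genes with large changes outside these groups included the growth factor gene Igf1, up 9.89-fold, and the matrix gene Cilp, up 13.0-fold. The immediate early list was not called (median 0.06, adjusted p = 0.811), but the transcription factor gene Myc fell 8.39-fold (-3.07 ± 0.13). Aspm, which acts at spindle poles, rose 11.7-fold and the centromere gene Cenpf 10.1-fold. The protease gene Adamts16 rose 10.6-fold, the dynein chain gene Dync1i1 10.1-fold, Enpp3 by 3.26 ± 0.27 and the calcium pump regulator gene Mrln 9.16-fold. The carbonic anhydrase gene Car6 fell 40.5-fold, the lipid enzyme genes Acox2 and Acot2 14.1-fold and 13.4-fold, the branched-chain aminotransferase gene Bcat1 by 3.70 ± 0.14, Cdsn by 3.57 ± 0.45 and the stress transcription factor gene Atf3 11.3-fold. Among the genes followed in every contrast, the hexokinase gene Hk2 fell 1.73-fold (adjusted p = 0.0055) and the mTOR inhibitor gene Deptor rose 1.73-fold (adjusted p = 0.0141). Arrdc4, a paralog of Txnip, was near the lower end of the intensity scale and changed by 0.25 ± 0.18 (adjusted p = 0.347), and the glucose transporter gene Slc2a4 by 0.02 ± 0.54 (adjusted p = 0.983). Signal above background was not shown in a group with a mean under 3 on the log2 scale, a bound chosen after the data were seen. Slc7a11, Acox2, Aspm, Mrln and Dync1i1 had such a group. Low signal may have shrunk their changes, and their choice for a large change or a small p may have inflated them. A dim second probe set of Slc7a11 was not called (-0.08, adjusted p = 0.859), and neither were those of Ckm and Rrm2. The count fell to 2193 and 2046 without control replicate 1 or 2 at 1 mM, and to 2060 without control replicate 2 at 10 mM.

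The same comparison of glucose levels after knockdown asks whether the response depends on Baf60c. Txnip rose 93.1-fold (6.54 ± 0.24, adjusted p = 3.97e-05), Slc7a11 fell 72.0-fold (-6.17 ± 0.16) and Cth fell 20.6-fold (-4.36 ± 0.12), each with n = 2 per group. Adamts16 rose 17.9-fold, the surface glycoprotein gene Cd200 16.3-fold and Map3k7cl 15.7-fold, while the secreted factor gene Ostn (musclin) fell 29.2-fold and Car6 35.9-fold. limma called 3342 genes, 1936 higher and 1406 lower, 1449 of them by at least 2-fold. With each array centred on its median the split turned, from 57.9% to 46.9% of calls higher, while the median of all genes moved by less than 0.1.

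ATF4 and amino acid response genes fell in 32 of 33 members, also when adjusted over the list alone, with Trib3 down 19.9-fold and Ddit3 by 3.34 ± 0.13. The median was -2.24 (adjusted p = 6.87e-28, and adjusted p = 0.0429 with an estimated correlation). Of 21 chaperone and unfolded protein response genes 20 fell (21 adjusted over the list alone), with Sdf2l1 down 21.5-fold and Hspa5 by 2.89 ± 0.15. The median was -1.61 (adjusted p = 6.05e-19, but adjusted p = 0.0679 with an estimated correlation). NRF2 and pentose phosphate genes fell in 9 of 13 members (10 adjusted over the list alone), Hmox1 by 2.37 ± 0.14 and Gclm by 1.63 ± 0.13. The median was -1.39 (adjusted p = 2.04e-08, but adjusted p = 0.0523 with an estimated correlation). Interferon response genes fell in 7 of 21 members (9 adjusted over the list alone), with Usp18 down by 2.25 ± 0.22. The median was -0.46 (adjusted p = 0.000272, but adjusted p = 0.0750 with an estimated correlation). Cell cycle genes rose in 23 of 28 members (25 adjusted over the list alone), Aurkb by 2.71 ± 0.20 and Top2a by 2.53 ± 0.16. The median was 1.86 (adjusted p = 2.56e-12, but adjusted p = 0.138 with an estimated correlation).

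Muscle genes also rose in knockdown cells. Of 26 myogenic differentiation genes 20 rose and 6 did not pass (22 rose adjusted over the list alone). The sarcomere gene Myom1 rose 4.86-fold, Myod1 5.71-fold and the Z-disc gene Ldb3 by 2.00 ± 0.15. The median was 1.08 (adjusted p = 1.12e-10, but adjusted p = 0.138 with an estimated correlation). Of 14 fast fibre genes 11 rose and 3 did not pass, also when adjusted over the list alone, among them the calsequestrin gene Casq1 (2.37 ± 0.31) and the calcium pump gene Atp2a1 (2.05 ± 0.23). The median was 1.08 (adjusted p = 4.23e-06, but adjusted p = 0.138 with an estimated correlation). Slow fibre genes rose in 7 of 13 members and fell in 2 (8 and 2 adjusted over the list alone), with Mb up by 1.91 ± 0.24 and Atp2a2 down by 1.03 ± 0.14. The median was 0.59 (adjusted p = 0.0188, but adjusted p = 0.240 with an estimated correlation). Extracellular matrix genes rose in 18 of 26 members (19 rose and 1 fell adjusted over the list alone), Thbs1 6.68-fold. The median was 0.83 (adjusted p = 1.4e-08, but adjusted p = 0.0750 with an estimated correlation). Of 11 fibroblast and smooth muscle markers 6 rose (7 adjusted over the list alone), Dpt by 2.38 ± 0.17 and the myosin light chain gene Myl9 by 1.76 ± 0.21. The median was 0.81 (adjusted p = 0.00725, but adjusted p = 0.138 with an estimated correlation). Undifferentiated myoblast markers had a median of 0.10 (3 rose, 2 fell, adjusted p = 0.908; 3 and 4 adjusted over the list alone). For adipocyte markers it was -0.32 (1 rose, 1 fell, adjusted p = 0.0823; 1 and 2 adjusted over the list alone). The macrophage markers Cd68 (-0.99 ± 0.28) and Ptprc (-0.67 ± 0.17) fell among 7, with 2 falls adjusted over the list alone, at a median of -0.25 (adjusted p = 0.162). For Ptprc a group mean was 2.41, so signal above background was not shown.

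The remaining genes with the largest changes in knockdown cells were Ranbp3l, Cilp, Tceal7, Tecrl, Scn7a and Cdh18, up by 3.81, 3.76, 3.67, 3.55, 3.29 and 3.16, and Rab39b, Acot2, Tenm4 and Acox2, down 16.7-fold, 14.5-fold, 13.0-fold and 12.5-fold. By the same bound, signal above background was not shown in a group of Slc7a11, Ostn, Rab39b, Acox2, Cd200, Map3k7cl, Tceal7, Tecrl and Arrdc4. Low signal may have shrunk these changes. For all but Arrdc4, the choice as the largest changes may have inflated them. Dim second probe sets of Rab39b (-0.44, adjusted p = 0.160) and Tenm4 (-0.60, adjusted p = 0.0767) were not called. Hk2 fell 1.77-fold (adjusted p = 0.00436), Deptor rose 2.40-fold (adjusted p = 0.00192) and Arrdc4 rose 1.59-fold (adjusted p = 0.0337). Slc2a4 changed by -0.70 ± 0.54 (adjusted p = 0.392). The count fell to 1903 and 2068 without knockdown replicate 1 or 2 at 10 mM.

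The glucose responses of both cell types were then set side by side. Of the 3372 genes called in control cells, 96.7% had the same sign in knockdown cells and 69.2% (2332) were called in the same direction. Of the 3342 called in knockdown cells, 97.1% had the same sign and 69.8% were called in control cells. Independent lists of these sizes would share 256.2 rises and 170.2 falls, against 1288 and 1044 observed. Across genes, which are not independent, the changes correlated at r = 0.83 with a slope of 0.85, and 6 genes were called in opposite directions.

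**Figure D2:**
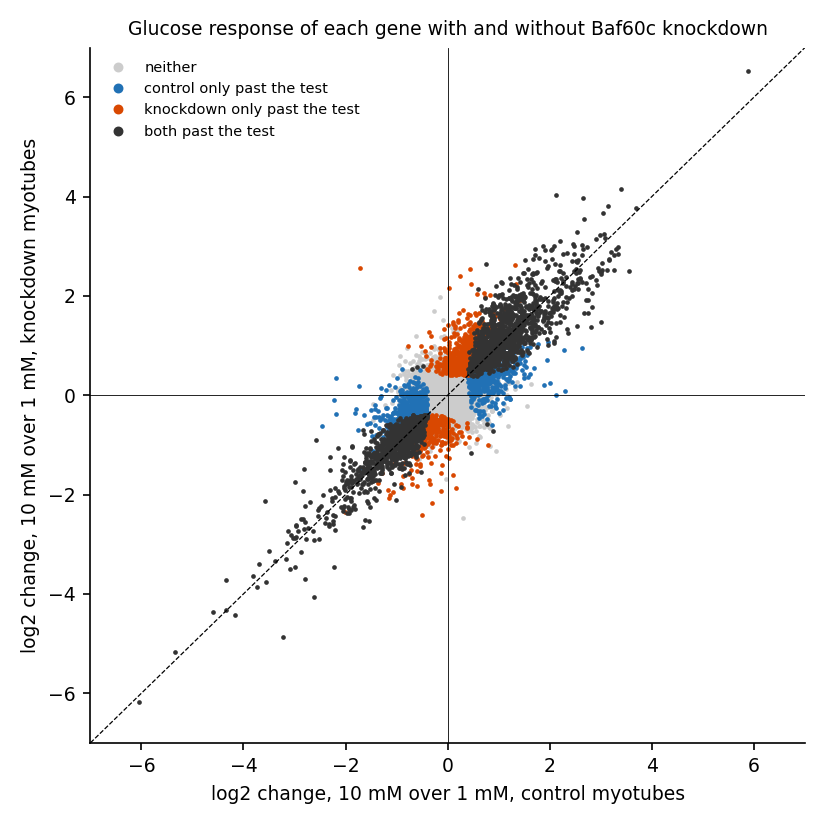
Log2 change from 1 mM to 10 mM glucose of each of the 13308 tested genes in control myotubes (horizontal axis) against knockdown myotubes (vertical axis); the dashed line marks equal changes and colours show which comparisons passed the test. The genes lie along the line, with r = 0.83 across genes.

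The comparison of knockdown with control cells at 1 mM glucose asks which genes depend on Baf60c when glucose is low. Several muscle genes were among the largest falls. The M-band gene Myom1 fell 8.03-fold (-3.00 ± 0.16, adjusted p = 0.00207), the small heat shock protein gene Hspb7 8.43-fold (-3.07 ± 0.23), Mb 7.23-fold (-2.85 ± 0.24) and Atp2a1 6.91-fold (-2.79 ± 0.23), each with n = 2 per group. limma called 198 genes, 31 higher and 167 lower, 146 of them by at least 2-fold, and 2115 genes had an unadjusted p under 0.05.

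Of 26 myogenic differentiation genes 15 fell, 0 rose and 11 did not pass, and 21 fell when adjusted over the list alone. The embryonic myosin gene Myh3 fell by 2.23 ± 0.15, the giant sarcomere gene Neb by 1.87 ± 0.15 and the transcription factor gene Mef2c by 2.17 ± 0.18. A dim second probe set of Mef2c was at -1.04 and not called (adjusted p = 0.188). The list median was -1.02 (adjusted p = 2.99e-23, but adjusted p = 0.150 with an estimated correlation). Fast fibre genes fell in 7 of 14 members (10 adjusted over the list alone), among them Myh1 (-2.01 ± 0.21), Tnnc2 (-1.73 ± 0.17) and Casq1 (5.04-fold). The median was -1.12 (adjusted p = 1.03e-08, but adjusted p = 0.150 with an estimated correlation). Slow fibre genes fell in 5 of 13 (10 fell and 1 rose adjusted over the list alone), among them Myh7 (-1.71 ± 0.14), Myoz2 (-1.41 ± 0.16) and Tnni1 (-1.22 ± 0.17). The median was -1.08 (adjusted p = 9.06e-08, but adjusted p = 0.150 with an estimated correlation). In the list of KATP channel and calcium signalling genes 5 of 22 fell (10 adjusted over the list alone). Those named were genes of calcium release and its kinase: the ryanodine receptor gene Ryr1 (-1.54 ± 0.13), Trdn (-2.15 ± 0.21), the calcium channel gene Cacna1s (-1.76 ± 0.17) and Camk2a (-1.11 ± 0.18). A dim second probe set of Ryr1 was at -0.29 and not called (adjusted p = 0.532). The list median was -0.37 (adjusted p = 1.33e-05, but adjusted p = 0.150 with an estimated correlation). In glycogen metabolism 1 of 13 genes fell, the muscle phosphorylase gene Pygm (7.10-fold), and 3 fell adjusted over the list alone. The median was -0.32 (adjusted p = 0.00972, but adjusted p = 0.150 with an estimated correlation).

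Markers of other cell types were not called as lists at 1 mM. Undifferentiated myoblast markers had a median of 0.02 (adjusted p = 0.713), macrophage markers 0.01 (adjusted p = 0.624), adipocyte markers 0.06 (adjusted p = 0.811), and fibroblast and smooth muscle markers 0.27 (adjusted p = 0.0608). The last list was called upward with a stricter filter (0.0317), without knockdown replicate 2 at 1 mM (0.0481) and without either control array at 10 mM (0.0444), and in the fry test (0.0339). limma called 0 members of these 4 lists over all genes, and adjusted over the list alone 4 fibroblast and smooth muscle markers rose and 1 fell. The ATF4 and cell cycle lists, which moved with glucose, had medians of -0.01 (adjusted p = 0.796) and 0.05 (adjusted p = 0.476), and the cell cycle list was called upward without knockdown replicate 2 at 1 mM (0.0309).

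Among further falls were the actin-binding protein gene Ablim3 (8.16-fold), Pgm5 (6.87-fold), the fatty acid transporter gene Cd36 (6.57-fold) and Fxyd6 (5.71-fold), the glycolytic genes Eno3 (-1.30 ± 0.14) and Pfkm (-1.31 ± 0.20), the muscle cytochrome oxidase genes Cox8b (-1.75 ± 0.23) and Cox6a2 (-0.73 ± 0.12), the ubiquitin ligase gene Trim63 (-1.37 ± 0.22) and the secreted factor genes Fst (-1.30 ± 0.15) and Fndc5 (-1.34 ± 0.23). The largest rises were those of Slfn2 (3.58-fold), P2rx3 (1.53 ± 0.25), Dthd1 (2.80-fold), Defa40 (1.43 ± 0.19), Igfbp2 (2.62-fold), Capn6 (2.54-fold), the chemokine gene Ccl2 (2.53-fold), Ctla2a (1.23 ± 0.21), Arap2 (1.21 ± 0.20) and Mgam (1.12 ± 0.19), and Angptl4 rose by 0.89 ± 0.13. For Cd36, Fxyd6, Myh7, P2rx3, Defa40 and Mgam a group mean lay under 3, so signal above background was not shown in that group. Low signal may have shrunk their changes, and their choice for a large change or a small p may have inflated them. Deptor was at -0.82 ± 0.17 (adjusted p = 0.0745), and its second probe set at -0.95 passed the test (adjusted p = 0.0288). Txnip (-0.09 ± 0.24), Arrdc4 (-0.18 ± 0.18), Hk2 (-0.09 ± 0.13) and Slc2a4 (-0.54 ± 0.54) were not called. Without control replicate 1 or 2 at 1 mM the count was 60 or 30, without knockdown replicate 1 or 2 at 1 mM 111 or 77, without either control array at 10 mM 123 and without either knockdown array at 10 mM 129. A stricter filter gave 437 calls (129 higher, 308 lower), an intensity trend 598 (191 and 407) and the 4 arrays alone 18 (0 and 18), which moved the share of higher calls from 15.7% to 29.5%, 31.9% and 0%. Of the 40 named genes past the test, 8 stayed past it under all settings tried.

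The comparison at 10 mM asks the same at the higher glucose level. Several muscle genes were again among the largest falls. Mb fell 4.63-fold (-2.21 ± 0.24, adjusted p = 0.018), the fast myosin gene Myh4 4.36-fold (-2.13 ± 0.34), the Z-disc gene Actn2 4.58-fold and the follistatin gene Fst, an inhibitor of myostatin, 4.76-fold (-2.25 ± 0.15, adjusted p = 0.00325), each with n = 2 per group. Smooth muscle genes were among the rises, with the calponin gene Cnn1 up 4.84-fold (2.28 ± 0.27, adjusted p = 0.0242). limma called 149 genes, 57 higher and 92 lower, 102 of them by at least 2-fold, and 1807 genes had an unadjusted p under 0.05.

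Of 26 myogenic differentiation genes 9 fell, 0 rose and 17 did not pass, and 19 fell when adjusted over the list alone. Among them were Ckm (-1.73 ± 0.14), Myom1 (-1.78 ± 0.16) and Myh3 (-1.30 ± 0.15). Dim second probe sets of Ckm (-0.06, adjusted p = 0.908) and Mef2c (-1.59, adjusted p = 0.0764) were not called. The list median was -0.81 (adjusted p = 4.62e-20, but adjusted p = 0.144 with an estimated correlation). Slow fibre genes fell in 4 of 13 members (11 fell and 1 rose adjusted over the list alone), among them Myoz2 (-1.45 ± 0.16) and Myh7 (-1.13 ± 0.14). The median was -0.98 (adjusted p = 6.63e-12, but adjusted p = 0.144 with an estimated correlation). Fast fibre genes fell in 3 of 14 (7 adjusted over the list alone): Myh4, Myh1 (-1.27 ± 0.21) and Tnnc2 (-1.10 ± 0.17). The median was -0.75 (adjusted p = 2.42e-06, but adjusted p = 0.223 with an estimated correlation). KATP channel and calcium signalling genes fell in 5 of 22 (9 adjusted over the list alone), with Cacna1s at -1.37 ± 0.17, Ryr1 at -1.10 ± 0.13 and Trdn at -1.41 ± 0.21. The second probe set of Ryr1 was not called (-0.35, adjusted p = 0.517). The list median was -0.37 (adjusted p = 9.68e-08, but adjusted p = 0.170 with an estimated correlation).

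Extracellular matrix genes had a median of 0.27 (adjusted p = 3.8e-06, but adjusted p = 0.170 with an estimated correlation). Thbs1 (0.93 ± 0.13) and the periostin gene Postn (2.95-fold) rose, 24 of 26 did not pass, and 6 rose adjusted over the list alone. Of 11 fibroblast and smooth muscle markers 3 rose and 8 did not pass (3 rose and 1 fell adjusted over the list alone): Cnn1, Myl9 (2.36-fold) and Tagln (2.17-fold). The median was 0.20 (adjusted p = 0.0369, but adjusted p = 0.30 with an estimated correlation), and the call was lost at 0.0650 without either knockdown array at 1 mM, at 0.109 without control replicate 1 at 10 mM, and at 0.060 or 0.0570 without knockdown replicate 1 or 2 at 10 mM. Undifferentiated myoblast markers had a median of -0.19 (adjusted p = 0.106, and called downward at 0.0142 with a stricter filter), macrophage markers -0.04 (adjusted p = 0.945) and adipocyte markers 0.04 (adjusted p = 0.940). limma called 0 members of these 3 lists over all genes, and adjusted over the list alone 1 adipocyte marker fell.

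Other falls were those of the chymotrypsinogen gene Ctrb1 (6.03-fold), Cd36 (5.68-fold), the heat shock protein gene Hspb3 (5.23-fold), the actin-binding gene Abra (4.32-fold), Pgm5 (4.17-fold) and Trp53i11 (4.08-fold). Rises included the growth factor gene Vegfc (3.05-fold), the Wnt signalling gene Rspo2 (3.04-fold), Trabd2b (1.60 ± 0.16), Try4 (1.56 ± 0.22), Serpinb9e (2.94-fold), Igfbp2 (2.82-fold), Capn6 (2.77-fold), Trbv13-2 (1.46 ± 0.24), the prostaglandin synthase gene Ptgs2 (1.36 ± 0.19) and the death receptor gene Fas (0.82 ± 0.13). For Ctrb1, Hspb3, Rspo2 and Serpinb9e a group mean lay under 3, so signal above background was not shown in that group. Low signal may have shrunk their changes, and their choice as the largest changes may have inflated them. Deptor (-0.34 ± 0.17), Txnip (0.56 ± 0.24), Arrdc4 (0.24 ± 0.18), Hk2 (-0.12 ± 0.13) and Slc2a4 (-1.27 ± 0.54) were not called. The count was 28 without either control array at 1 mM, 76 without either knockdown array at 1 mM, 11 without control replicate 1 at 10 mM, and 0 without control replicate 2, knockdown replicate 1 or knockdown replicate 2 at 10 mM. No filter gave 69 calls, a stricter filter 291, an intensity trend 467 and the 4 arrays alone 6, and 0 of the 40 named genes past the test stayed past it under all settings.

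**Figure D3:**
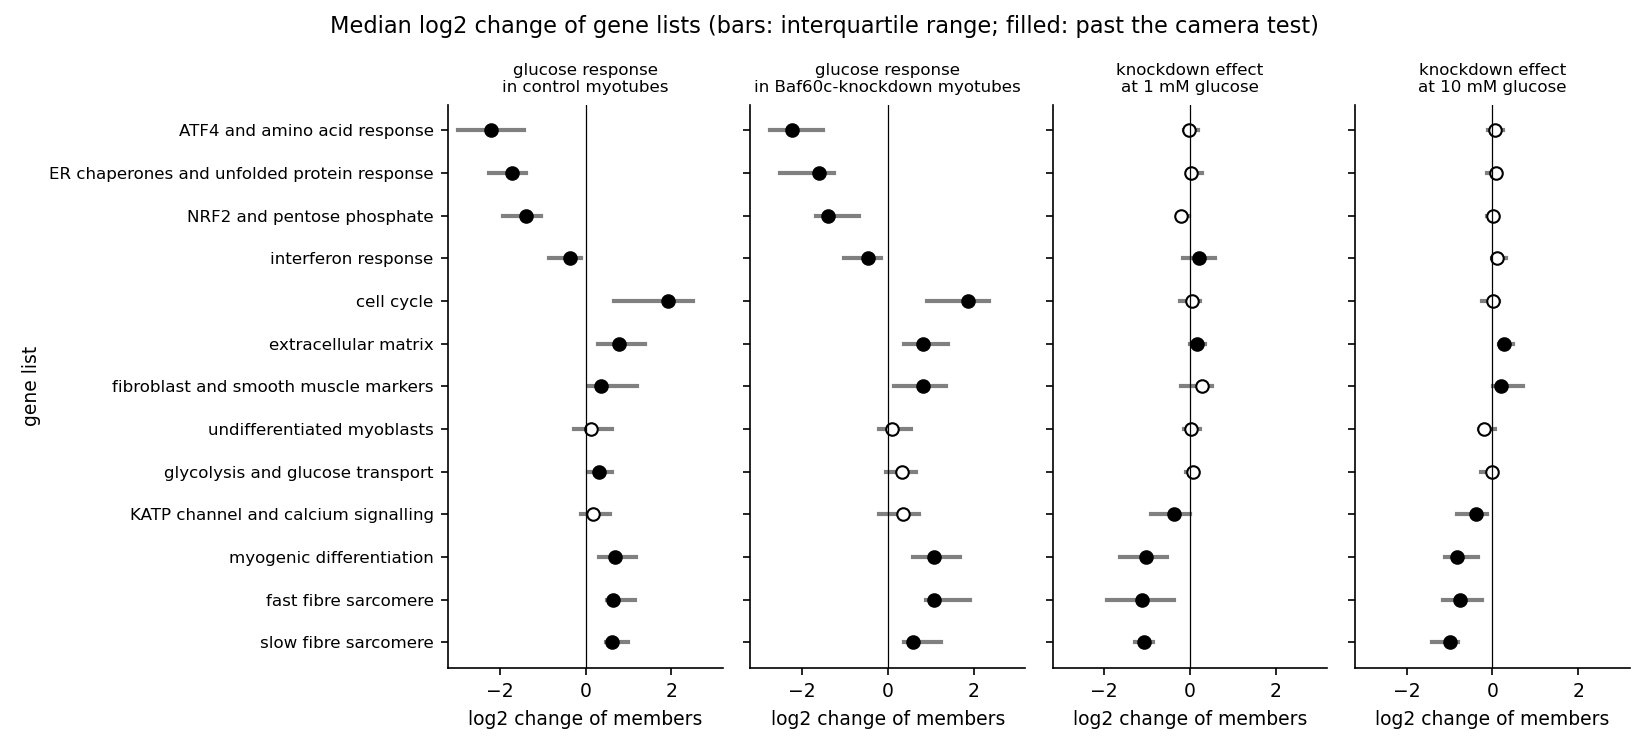
Median log2 change of the members of 13 gene lists (points) with the interquartile range of the members (bars) in 4 contrasts; filled points passed camera at its preset correlation. The ATF4, chaperone and NRF2 lists lie below 0 and the cell cycle list above 0 with glucose in both cell types, and the myogenic, fast fibre and slow fibre lists lie below 0 after knockdown at both glucose levels.

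Of the 198 genes called for the knockdown at 1 mM, 91.9% had the same sign at 10 mM and 32.8% (65) were called there in the same direction. Of the 149 called at 10 mM, 91.3% had the same sign at 1 mM and 43.6% were called. The shared genes were 7 rises and 58 falls, against 0.133 and 1.15 for independent lists of these sizes. Across genes, which are not independent, the knockdown effects correlated at r = 0.41 with a slope of 0.38.

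The interaction asks whether the glucose response differed between knockdown and control cells. limma called 0 genes (smallest adjusted p = 0.235), with 1049 genes at an unadjusted p under 0.05 against 665.4 given by chance. With an intensity trend and robust prior 1 gene was called, Thbs1, named after its value was seen. Its rise with glucose was larger in knockdown cells by 1.07 (adjusted p = 0.0104 with the trend and 0.336 without). The genes with the smallest unadjusted p, none past the test, were Tns4 (1.40 ± 0.16), Fgf5 (2.11 ± 0.28), Trabd2b (1.56 ± 0.22), Kcnn3 (1.89 ± 0.27) and Serpinb9e (1.68 ± 0.24) in the positive direction. In the negative direction they were Iqgap3 (-1.43 ± 0.17), Rabggtb (-1.63 ± 0.20), Best3 (-2.12 ± 0.28), Macrod1 (-1.61 ± 0.22) and Dthd1 (-1.24 ± 0.19). The differences for Txnip (0.65 ± 0.35), Deptor (0.48 ± 0.24), Arrdc4 (0.41 ± 0.26), Hk2 (-0.03 ± 0.19) and Slc2a4 (-0.72 ± 0.76) were not called either. Of the 31 lists, myogenic differentiation genes stood apart with a median of 0.31 (adjusted p = 0.000745, but adjusted p = 0.588 with an estimated correlation), and 5 members were past the test, all upward, adjusted over the list alone. Fast fibre genes had a median of 0.48 (adjusted p = 0.0138, but adjusted p = 0.588 with an estimated correlation), with 1 member past the test, upward, adjusted over the list alone. The slow fibre list had a median of -0.01 (adjusted p = 0.940). Without control replicate 1 at 10 mM both list calls were lost (adjusted p = 0.0663 and 0.294), and the fast fibre call was also lost without control replicate 1 at 1 mM (0.0614), knockdown replicate 2 at 1 mM (0.0633) or knockdown replicate 2 at 10 mM (0.0900). In the simulated data, 3% of genes with an interaction of 1 on the log2 scale were recovered, so differences of that size between the responses were mostly not detectable with 2 arrays per group.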

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

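The tests on undifferentiated cells, on the myotube share at 10 mM glucose, on muscle genes changing in proportion at both glucose levels, and on the probe sets outside the gene table were chosen after the results were seen. The bounds of the other tests were written before their own values were seen, but the restriction to list members at a middle level was added after the data had been examined.

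The knockdown effect on myogenic and fast fibre genes differed between the glucose levels in camera at its preset correlation. It did not with an estimated correlation (adjusted p = 0.588 for both lists) or in the fry test (adjusted p = 0.232 and 0.25). The slow fibre list did not differ in camera (-0.01, adjusted p = 0.940). The glucose response was larger in knockdown than in control cells by a median of 0.4844 for the fast fibre list and 0.3129 for the myogenic list on the log2 scale, so the deficit of these lists was smaller at 10 mM. The shared target probe set was also less reduced at 10 mM (-1.98) than at 1 mM (-2.62). That difference of 0.64 did not pass the limma test (adjusted p = 0.673). Whether a weaker knockdown at 10 mM accounts for the smaller deficit was not tested. Compression at the ends of the intensity scale predicts no difference among members at a middle level, but their median was 0.4807 over 28 genes, which argues against it. Whether 1 array decides the difference stays open: the lowest myogenic median was 0.25, without knockdown replicate 1 at 1 mM (adjusted p = 0.010), and the list calls were lost without control replicate 1 at 10 mM (adjusted p = 0.0663 and 0.294). No biological explanation was tested.

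The myogenic and fibre lists had lower medians after knockdown at both glucose levels. However, no camera call held with an estimated correlation (adjusted p = 0.150 at 1 mM, 0.144 to 0.223 at 10 mM). The fry test, which does not compare members with other genes, was past the threshold for the myogenic, fast and slow fibre lists. Its adjusted p was 0.00247, 0.00599 and 0.00441 at 1 mM, and 0.00578, 0.0350 and 0.00578 at 10 mM. After each array was centred, the myogenic medians were -0.8066 at 10 mM and -0.9678 at 1 mM. Centring could change little, since the array medians already lay between 5.89 and 6.02. It speaks only against a shift shared by all genes of an array, and it did not test a shift that depends on intensity. A smaller share of myotubes was expected to lower all members alike, but the spread of the members' changes was 2.817 times their standard error at 10 mM and 4.006 times at 1 mM. That spread went past the bound written beforehand. The bound assumed that probe sets respond by the same factor and that other cells express no members, and neither was measured. Six4 (-0.02 at 1 mM) and Tpm1 (0.34 at 10 mM) showed little or no fall. About a line proportional between the glucose levels the spread was 1.117 times the standard error for the 36 members at a middle level (slope 0.622). For all 53 it was 1.561 times. Lower expression per myotube could give proportional changes as well. The undifferentiated myoblast medians of 0.01721 at 1 mM and -0.1918 at 10 mM stayed short of the rise that the proportional test required for a smaller share of myotubes. The call downward at 10 mM with a stricter filter (adjusted p = 0.0142, against 0.106) goes against more undifferentiated cells, but at 1 mM the members went both ways. So fewer myotubes and lower expression per myotube cannot be told apart here, and the lower muscle genes after knockdown may reflect either. Effects of the shRNA on genes other than Baf60c, and differences between the transduced cell populations, were not tested.

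The cell cycle list had a higher median at 10 mM glucose, and so had the myogenic list. Neither camera call held with an estimated correlation (adjusted p = 0.166 in control and 0.138 in knockdown cells). Both lists were past the threshold in the fry test, which does not compare members with other genes. Its adjusted p for the cell cycle list was 0.00108 in control and 0.00117 in knockdown cells, and for the myogenic list 0.00185 and 0.000452. The myogenic medians of 0.6833 in control and 1.084 in knockdown cells gave no sign of a smaller share of myotubes at 10 mM. They cannot exclude it, since the share and the expression per myotube were not measured apart. After centring, the cell cycle medians were 1.88 in control and 1.761 in knockdown cells, which again speaks only against a shift shared by all genes of an array. More undifferentiated cells cannot be told apart from cycling in the cells present. The undifferentiated myoblast medians were 0.1264 in control and 0.09708 in knockdown cells, with members in both directions. No biological explanation was tested.

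In 6 genes the glucose response was called in opposite directions in control and knockdown cells, although none of the differences passed the adjusted test. The differences were 1.071 for 1810014B01Rik (adjusted p = 0.40), 1.166 for B330016D10Rik (0.30), 1.229 for Slc41a3 (0.289), -1.609 for Macrod1 (0.235), -1.344 for Myh7b (0.30), whose signal lay near the lower end of the scale and was not shown to be above background, and -1.63 for Rabggtb (0.235).

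Among 8926 probe sets outside the gene table, with no gene or several, 67 passed the test for the glucose response in control cells (25 higher, 42 lower) and 39 in knockdown cells (6 higher, 33 lower). For the knockdown effects and the interaction limma called 0 of them in this separate fit. The shared Smarcd3 and Chpf2 probe set was among them. Fitted with the tested genes, it passed the limma test after knockdown (adjusted p = 0.00313 at 1 mM and 0.0171 at 10 mM). The count of 0 therefore does not show that no probe set outside the gene table changed with knockdown.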

How the results depend on the processing

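The fit of the shared target probe set, the list members at a middle level, the symbol families and the probe sets outside the gene table were added after the data had been examined, and the settings here were chosen before. Glucose counts stayed within 1.5 times of 3372 and 3342 under every setting except some with 1 array left out, and 102 of 127 and 111 of 132 named genes past the test stayed past it under all settings. The knockdown counts depended on the setting. No called named gene changed direction under any setting. The array values carry no detection call, so signal over background limits the dim genes: Arrdc4 and Slc2a4 lie near the lower end, and the log2 filter value was 2.30. Where the cause of a change is not given by construction (fewer genes or arrays), the cause was not tested.

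Without a filter the knockdown at 10 mM had 69 calls, and the shares called in the same direction were 66.2% and 67.9% for glucose and 26.3% and 52.2% for knockdown. With the stricter filter the knockdown had 437 calls at 1 mM and 291 at 10 mM, 152 and 104 of them shared with the reported calls. There were 4 lists for the interaction (undifferentiated myoblasts and interferon response in addition, adjusted p = 0.00400 and 0.0426), and sharing was 97.3%, 72.5%, 74.0% and 51.9%. With the intensity trend the counts were 598, 467 and 1 (knockdown at 1 mM, at 10 mM, interaction), with 191 and 141 shared, and a glucose share of 71.8%. With the 4 arrays of a contrast alone the knockdown had 18 and 6 calls. With an estimated correlation 2, 1, 0, 0 and 0 lists were called, ATF4 and NRF2 in control cells and ATF4 in knockdown cells.

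Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.0385 to 0.108 over 6 pairs of groups. With the replicate block the counts were 3111, 3102, 134, 73 and 0, and 56.2% of the knockdown calls at 10 mM were called at 1 mM.

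Uncalled genes that changed sign were Slc2a4 with glucose in control cells, at -0.089 with quantile normalization and -0.027 with centring, and Smarcd1 at 0.28 with glucose in knockdown cells and -0.079 after knockdown at 10 mM with the mean of its probe sets.

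With each array left out in turn, the lone array of a group was assumed to vary like the other groups. Counts ranged from 2046 to 3251 and 1903 to 3185 for glucose, 30 to 129 and 0 to 76 for knockdown, and lists from 0 to 2 for the interaction. Of glucose calls in control cells 94.9% to 97.9% had the same sign and 53.2% to 81.9% were called in knockdown cells, and in the reverse direction 96.1% to 98.3% and 52.6% to 79.9%. For knockdown calls at 1 mM these shares were 90.1% to 98.3% and 0% to 41.6%, and at 10 mM 85.5% to 90.9% and 32.1% to 72.7%, with no share where no gene was called at 10 mM. Uncalled genes that changed sign were Smarcd1 (-0.039 to 0.54), Smarcd2 (-0.40 to 0.0029) and Slc2a4 (-0.40 to 0.44) with glucose in control cells, and Smarcd1 (-0.29 to 0.24) and Slc2a4 (-1.52 to 0.11) in knockdown cells. After knockdown at 1 mM they were Txnip (-0.43 to 0.26), Arrdc4 (-0.41 to 0.059) and Slc2a4 (-1.36 to 0.27), and at 10 mM Smarcd1 (-0.20 to 0.32) and Smarcd2 (-0.19 to 0.21). For the interaction they were Smarcd1 (-0.56 to 0.013), Smarcd2 (-0.29 to 0.12), Hk2 (-0.13 to 0.069) and Slc2a4 (-1.54 to 0.092). Among called named genes, 492 calls were lost over the 8 left-out arrays, 83 with the 4 arrays alone, 34 without a filter, 27 with the replicate block, 10 with centring, 6 with quantile normalization, 5 with the mean of probe sets and 3 with the trend.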

Other observations

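The glycolysis and lipid lists, chosen beforehand, and the symbol families, chosen after seeing the data, were read beside the comparisons above. The test across genes in the last paragraph was set out before its result was seen. Lipid and fuel genes moved with glucose in both directions. In control cells the fatty acid oxidation list had a median of 0.37 (7 of 24 rose, 2 fell, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0150, but adjusted p = 0.259 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose 2.87-fold and Angptl4 by 1.12 ± 0.13, while the thioesterase gene Acot2 fell 13.4-fold. In knockdown cells the median of 0.24 was not called (adjusted p = 0.0524), but it was with no filter (0.00483), a stricter filter (0.0361), quantile normalization (0.0477), and without knockdown replicate 2 at 1 mM (0.0231) or replicate 1 at 10 mM (0.0286). Cd36 rose there by 1.69 ± 0.24, from dim signal not shown to be above background. Of 21 glycolysis and transport genes 8 rose and 2 fell in control cells (9 and 2 adjusted over the list alone). Pgam2 rose 2.67-fold from dim signal, and Hk2 and the transporter gene Slc2a1 (-0.60 ± 0.13) fell, the latter not on a dim second probe set (-0.26, adjusted p = 0.284). The median of 0.32 passed the test (adjusted p = 0.0182, but adjusted p = 0.166 with an estimated correlation), except without control replicate 1 at 1 mM (0.0743) or at 10 mM (0.0519) and with a stricter filter (0.0705). In knockdown cells the median of 0.33 did not pass (adjusted p = 0.0557), but it did with no filter (0.00509), quantile normalization (0.0477), and without knockdown replicate 2 at 1 mM (0.0354) or at 10 mM (0.0359), so no difference between the cell types is shown. In control cells the glycogen-binding gene Stbd1 fell 4.82-fold and Pygm rose by 0.89 ± 0.25, and the glycogen list was not called (adjusted p = 0.942). Of 12 MondoA and ChREBP targets in control cells 3 rose and 1 fell, also adjusted over the list alone, among them Txnip and Rgs16 (1.12 ± 0.14) upward, at a median of 0.18 (adjusted p = 0.40). In oxidative phosphorylation, also in control cells, 29 of 33 genes did not pass, 3 rose and Cox6a2 fell by 0.90 ± 0.12 (1 rose and 1 fell adjusted over the list alone, median 0.20, adjusted p = 0.0482, but adjusted p = 0.166 with an estimated correlation). That call was lost without 5 of the arrays, at 0.0684 and 0.0953 without control replicate 1 or 2 at 1 mM, 0.0579 without either knockdown array at 1 mM and 0.160 without control replicate 1 at 10 mM, and also with centring (0.0602) and a stricter filter (0.0660).

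Secreted factors also moved with glucose in control cells. Of 17 myokine genes 9 rose and 4 fell (9 and 5 adjusted over the list alone). Fst rose 4.35-fold and Cxcl12 by 1.02 ± 0.13, and Ostn fell 9.37-fold to dim signal. The median was 0.91 (adjusted p = 0.0247, but adjusted p = 0.166 with an estimated correlation, and 0.0767 without control replicate 1 at 1 mM). In lysosome and autophagy 6 of 24 fell and 1 rose (7 and 2 adjusted over the list alone), Sqstm1 by -1.25 ± 0.13, at a median of -0.15 (adjusted p = 0.0482, but adjusted p = 0.259 with an estimated correlation). That call was lost without control replicate 1 at 1 mM (0.109) or at 10 mM (0.105) and without either knockdown array at 1 mM (0.0583), and also with quantile normalization (0.145) and a stricter filter (0.0674). In knockdown cells the myokine list had a median of 1.00 (10 rose, 3 fell, 11 and 4 adjusted over the list alone, adjusted p = 0.0188, but adjusted p = 0.138 with an estimated correlation), with Igf1 up 7.76-fold. The lysosome list had a median of -0.23 (2 rose, 7 fell, 2 and 8 adjusted over the list alone, adjusted p = 0.0188, but adjusted p = 0.195 with an estimated correlation), a call lost without knockdown replicate 1 at 1 mM (0.0585). The oxidative phosphorylation list had a median of 0.23 (4 rose, 1 fell, 2 and 1 adjusted over the list alone, adjusted p = 0.0408, but adjusted p = 0.146 with an estimated correlation). That call was lost without knockdown replicate 1 or 2 at 1 mM (0.0561 and 0.0996) and at 10 mM (0.0550 and 0.0724), and with centring (0.0638). Lists not called in control cells held called genes as well. Of 14 NF-kB and chemokine genes 7 fell and 2 rose (7 and 3 adjusted over the list alone), at a median of -0.49. The NF-kB list (adjusted p = 0.0704, but 0.0472 without control replicate 1 at 10 mM) held Ptgs2, down 7.33-fold, and Csf1, down by 1.33 ± 0.18. The FoxO list (0.384) held Klf15, down 4.62-fold to dim signal, and Ccng2, up by 1.29 ± 0.14. The clock list (0.918) held Ciart, down by 1.90 ± 0.24, and Bhlhe41, up by 1.05 ± 0.17. The cholesterol list (0.358) held Mvd, down by 1.25 ± 0.19, and the fatty acid synthesis list (0.907) Acss2, up by 1.03 ± 0.15. The hypoxia list (0.811) held Ero1a, down by 1.64 ± 0.15, and Lox, up by 0.98 ± 0.13. The p53 list (0.907) held Fas, up by 1.15 ± 0.13, and the mTOR list (0.811) Eif4ebp1, down by 1.28 ± 0.13. The KATP and calcium list (0.0805, but 0.0282 with no filter and 0.0495 without control replicate 1 at 10 mM) held Trdn, up by 1.21 ± 0.21, and the BAF list (0.811) Phf10 (-1.325 ± 0.14).

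At 1 mM glucose, 5 lists had higher medians after knockdown although limma called 0 of their members over all genes. They were the interferon response (0.22, adjusted p = 0.00315, but adjusted p = 0.150 with an estimated correlation), cholesterol synthesis (0.21, adjusted p = 0.00972, but adjusted p = 0.150 with an estimated correlation) and immediate early genes (0.28, adjusted p = 0.00972, but adjusted p = 0.150 with an estimated correlation). The others were extracellular matrix (0.15, adjusted p = 0.00972, but adjusted p = 0.273 with an estimated correlation) and hypoxia (0.19, adjusted p = 0.0315, but adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 3, 0, 4, 1 and 1 members rose in the same order. The hypoxia call was lost without control replicate 1 (0.221) or knockdown replicate 1 (0.0778) at 1 mM, and the cholesterol call without knockdown replicate 1 (0.152).

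Among 147 families of genes with a common symbol stem, camera called 5 for glucose in control cells and 6 in knockdown cells. Ddx helicase genes fell in 13 of 30 members in control (median -0.37) and 9 in knockdown cells (median -0.33). Kif motor genes rose in 13 and fell in 3 of 32 in control cells, Eif translation factor genes fell in 10 of 48 and Alg glycosylation genes in 5 of 12. Tspan genes rose in 6 of 17 in each cell type. In knockdown cells Col genes rose in 11 of 31, Utp ribosome assembly genes fell in 6 of 10, Snhg genes fell in 7 and rose in 1 of 15, and Myh genes rose in 6 and fell in 1 of 10. After knockdown Myh genes fell in 5 of 10 at 1 mM and 6 at 10 mM, while Ccl and Mmp genes at 1 mM (medians 0.38 and 0.41) and Col genes at 10 mM (0.19) were called upward with 1 of 13, 0 of 11 and 0 of 31 members past the limma test. None of these calls held with an estimated correlation (smallest adjusted p = 0.669). The Myh, Col and Kif families share genes with the muscle, extracellular matrix and cell cycle lists, so their calls are not separate from those lists.

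A hypothesis that the knockdown moves genes against the glucose response was tested across genes, which are not independent. The average knockdown effect and the average glucose effect correlated at r = -0.09694 (Spearman's rho -0.0199) over 13308 genes, above the -0.2 that the hypothesis required, so a general opposition is not supported. Over the 53 genes of the muscle lists r was -0.548 (rho -0.499), but this subset was taken up because both effects had been seen in it, so it tests nothing further.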
